A study of Mus musculus with 6 samples.

How the data were processed

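Tongue epithelium of 6 mice was profiled by 3'-end mRNA sequencing (QuantSeq, a kit that makes 1 tag near the poly(A) tail of each mRNA). Per the labels, 3 mice had floxed Ire1α alleles alone (WT) and 3 littermates also carried the tamoxifen-inducible keratin 14 Cre (KO). Groups and replicate numbers were taken from the sample titles, and the value columns were matched to samples by the library names in the labels, with 0 columns of values left unmatched.

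The authors deposited a table of 55421 genes with the normalised read count of each library, a signal on a linear scale that per the file headers is a normalised count. FastQC, STAR, featureCounts and DESeq2 are named in the submitters' processing notes, without versions. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The authors also deposited a table of called genes with log2 fold changes and their standard errors, a score (the Wald statistic), p-values, adjusted p-values and q-values, per the file headers. Its mean expression column matched the mean of the 6 libraries to within 0.051%, and 3 of its adjusted p-values were NA.

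Every normalised value in a library was a whole multiple of 1 step (100% of values to within 0.01 of a whole read), as it is when whole read counts are divided by 1 size factor per library. A step was worth 0.942, 0.873 and 1.31 in WT replicates 1 to 3 and 1.08, 0.862 and 0.953 in KO replicates 1 to 3, so a value of 0 allows up to 3 reads, or 2.59 to 3.92 in normalised units, for counting error only. The recovered totals were 4606309 to 6286153 reads. The 10 genes with the most reads took 20.3% to 25.8% of a library. Rows without a gene symbol (3192) held 0.077% to 0.119% of the values. They name genes by identifier and were kept. The libraries come from separate mice and each counted as 1 sample. Replicates of a group had a Spearman correlation across genes of 0.939 to 0.964.

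Normalised values were transformed to log2(value + 1) and genes with a value of at least 10 in at least 3 libraries were kept (10987 of the 21778 genes above 0 in at least 1 library). KO was compared with WT by limma 3.58.1 with an intensity trend and Benjamini-Hochberg adjustment at 0.05 in R 4.3.3. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Tests are two-sided. With 3 mice against 3, an exact permutation test of a single value cannot go below 0.1, so none was used.

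The gene lists were fixed before the data were examined from general knowledge of the unfolded protein response, keratinocytes and the other cells of the tongue. They cover UPR sensors and transducers, ER translocation, ER N-glycosylation, ER folding, ER-associated degradation, ER-Golgi transport, substrates of Ire1α-dependent decay (RIDD), the integrated stress response, basal keratinocytes, suprabasal and cornified cells, hard keratins of filiform papillae, stress keratins and alarmins, S phase, mitosis, p53 and apoptosis, cholesterol and fatty acid synthesis, NRF2 targets, interferon response, NF-kB and chemokines, immediate early genes, ribosomal proteins, mitochondrially encoded genes, and markers of taste buds, salivary gland, fibroblasts, skeletal muscle, endothelium, leukocytes, nerve and glia, melanocytes, erythrocytes and sex. The 26 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation 0 lists passed, and with the directional test of fry 1 list did, p53 and apoptosis (fry adjusted p = 0.00574). The mixed test of fry, which asks for changes in either direction, passed for p53 and apoptosis (adjusted p = 4.5e-04), RIDD substrates (4.0e-04), the integrated stress response (0.00366), stress keratins and alarmins (0.00730), filiform papillae (0.00730) and basal keratinocytes (0.0143). Some genes stand in 2 lists, namely Tnfrsf10b, Slc7a11 and Atf4. Of the 8 tested RIDD substrates, 1 passed the limma threshold over all genes, which was Tnfrsf10b, also in the p53 list. The mixed test was not repeated without Tnfrsf10b, so the RIDD result may rest on that gene.

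The genes named in the text follow a rule fixed before the data were examined. It takes Ern1 and Xbp1, then the 8 highest and 8 lowest log2 fold changes among called genes with no overlap of the groups and a mean value of at least 50, leaving out predicted genes. Not every gene the rule picks is named in the text. It adds the 2 tested members with the smallest p of each list on the UPR core, keratinocytes and the cell cycle, and 1 of each other list. The remaining members of the p53 and apoptosis list, Hbegf, Krt33b, Krt14, Krt5, Krt15, Krt6b and Mitf were named after their values were seen, as were the genes that open the last part of the closing section.

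The fit was tested on simulated counts for this comparison before it was run, with 10975 simulated genes tested and 200 changed by a known fold. It called 30.3% of genes changed 2-fold and 93.5% of genes changed 4-fold, and 4.9% of its calls were unchanged genes. A gene that did not pass may therefore have changed 2-fold. The simulated genes varied independently and the simulated libraries held no structure besides genotype, unlike the real ones, so these shares may not carry over. The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood, 190 genes called) and DESeq2 1.42.0 (371 genes called). Other alternatives were the pseudocount, the filter, the scaling (TMM, equal totals, quantile), weights per library, robust variance moderation, the replicate number as a block, the style of the library name as a covariate, and leaving out each library. Covariates for fibroblast and muscle transcripts and for Y-linked transcripts, and 1 surrogate variable (sva 3.50.0), were chosen after seeing the data, as were counts of list members without single libraries and the ribosomal list without the 10 tested genes of other function (Rps6k kinases, Rps19bp1 and Rps23rg1). Files were read with Python 3.11.15 and pandas 2.3.3.

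Of the gene identifiers, 55154 are in GENCODE M21 (GRCm38), which was used for positions and may not be the annotation the authors used. Of 918 protein-coding genes that lie wholly inside another protein-coding gene there, on either strand, 914 were listed at 0 in every library, against 22.8% of the other 21058. Among them were Rpl13 and Cox4i1, which every cell uses, Acta1 and Cxcl10, so a 0 for an enclosed gene says nothing about its expression. Genes that overlap a neighbour in part may have lost or gained reads, which applies to the named genes Sulf2, Adamtsl1, Irf7, Mbtps2, Rpl5, Amy1 and Polk. Reads of near-identical copies cannot be told apart for certain, which applies to Sprr1a and Sprr1b, Krt6b, Krt14, Krt17, the globins, Amy1, Trbc2, Rpl5 and Ifi27l2a. In all, 70 list members were at 0 in every library and entered no test. Of these, 53 are protein-coding with a position in GENCODE M21, of which 17 lie wholly inside another protein-coding gene, 14 overlap one in part and 22 overlap none. Among the 22 are Rpl24, Rpl35a and mt-Co2, which cells in general use, so a 0 outside enclosed genes is not evidence of silence either.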

Results

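Gene expression was measured in tongue epithelium from 6 mice, 1 library per mouse. In 3 mice both copies of the Ire1α gene (Ern1) carried loxP sites and no Cre recombinase was present (WT). In 3 littermates the same alleles were combined with a tamoxifen-inducible Cre driven by the keratin 14 promoter, which is active in basal keratinocytes (KO). All mice were given tamoxifen on 4 consecutive days and were harvested on day 5, and the epithelium was peeled off after 10 minutes of enzyme digestion at 37 °C. Ire1α is a sensor of unfolded protein in the endoplasmic reticulum (ER) that splices the Xbp1 mRNA, and the series was made to ask what its loss changes in the tongue lining. Libraries held 5911884, 5516801 and 4606309 reads in WT replicates 1 to 3 and 5202101, 6286153 and 5984402 in KO replicates 1 to 3. Between 16440 and 17529 genes were above 0 in a library. Values below are normalised read counts, given as mean ± SD with n = 3 mice per group unless stated otherwise.

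The targeted gene Ern1 (ENSMUSG00000020715, chromosome 11, 106394650 to 106487852, minus strand, GRCm38 in GENCODE M21) gave 102, 105 and 77.1 in WT replicates 1 to 3 and 78.0, 117 and 123 in KO replicates 1 to 3. Its level was 94.5 ± 15.2 in WT and 106 ± 24.5 in KO, a log2 fold change of 0.15 ± 0.24 (SE) that did not pass the test (limma adjusted p = 0.847). The library kit reads the 3' end of an mRNA and the labels do not name the exons removed, so a 3' tag outside the deleted part checks nothing about the genotype. Xbp1, whose mRNA is spliced by Ire1α, had 319 ± 145 in WT and 254 ± 99.5 in KO (log2 fold change -0.27, limma adjusted p = 0.813). Its values were 449, 346 and 162 in WT replicates 1 to 3 and 194, 369 and 199 in KO replicates 1 to 3. It was thus highest in WT replicates 1 and 2 and KO replicate 2, a division other than genotype that the closing section takes up. Counts of the whole gene do not separate spliced from unspliced Xbp1.

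In KO tongue epithelium, 11 of 19 tested genes of a list of p53 targets rose and 3 of 10 interferon response genes fell, by limma over all genes. The lists as wholes passed camera at a preset correlation, and had an adjusted p = 0.189 and an adjusted p = 0.394 with an estimated correlation. Ccng1, a cyclin and direct p53 target, rose from 88.1 ± 25.5 to 430 ± 59.3, which is 4.93-fold (log2 fold change 2.30 ± 0.22 (SE), limma adjusted p = 0.00113). Isg15, a ubiquitin-like protein induced by interferon, fell from 107, 1508 and 166 in the 3 WT libraries to between 4.76 and 8.62 in KO (log2 fold change -5.33 ± 0.77 (SE), limma adjusted p = 0.00737). Gria3, an AMPA-type glutamate receptor subunit, had the highest log2 fold change among the genes named by rule, from 5.20 ± 3.72 to 113 ± 12.8 (4.39 ± 0.44 (SE), limma adjusted p = 0.00113). Of 10987 genes tested with limma, 134 were higher and 64 lower in KO, 198 in all, and 1485 had an unadjusted p under 0.05. The groups did not overlap in 19.1% of tested genes, where chance gives 10% for 3 against 3. The count was 80 without WT replicate 2, 75 without KO replicate 1, 112 without KO replicate 2 and 68 without KO replicate 3, and without WT replicate 1 the genes lower in KO numbered 38. Outside these fits it was 82 with the style of the library names as a covariate, 590 with a weight per library and 371 with DESeq2 on the recovered reads. The name style, whose meaning the labels do not give, is partly aligned with genotype: WT replicates 1 and 2 and KO replicate 1 have one style and the other libraries another.

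The p53 and apoptosis list held 19 tested genes, of which 11 rose, 0 fell and 8 did not pass (14 rose and 1 fell when adjusted over the list alone). With edgeR 11 rose, and with DESeq2 12 rose and 1 fell. Its median log2 fold change was 1.37 (camera adjusted p = 5.1e-15; adjusted p = 0.189 with an estimated correlation). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose from 5863 ± 479 to 15032 ± 2567 (log2 fold change 1.35 ± 0.21 (SE), limma adjusted p = 0.0106). Mdm2, the ubiquitin ligase that degrades p53, rose from 216 ± 65.2 to 546 ± 10.9 (limma adjusted p = 0.0102). Tnfrsf10b, a death receptor for TRAIL, rose from 15.97 ± 1.40 to 80.3 ± 18.9 (log2 fold change 2.24 ± 0.27 (SE), limma adjusted p = 0.00305). Pmaip1 and Bbc3, which encode the pro-apoptotic proteins Noxa and Puma, rose by log2 fold changes of 3.52 and 1.76 from 1.33 ± 0.40 and 9.34 ± 2.17. Trp53inp1, Zmat3, Eda2r, Aen and Plk2 rose by 1.37 to 2.51 on the log2 scale. Sesn1, another p53 target, was 186 ± 35.8 in WT and 101 ± 13.0 in KO and did not pass over all genes (limma adjusted p = 0.0794, and 0.0458 without WT replicate 3), and DESeq2 called it lower (0.0344). In every KO library the mean of the list lay 1.07 to 1.39 log2 units above the WT mean. The number of members that rose was 7 without WT replicate 2, 6 without KO replicate 1 and 5 without KO replicate 3. Ccng1, Trp53inp1, Tnfrsf10b, Zmat3 and Eda2r passed whichever library was left out. Cdkn1a and Mdm2 did not pass without WT replicate 2, KO replicate 1 or KO replicate 3 (highest limma adjusted p = 0.0605 and 0.0552), Aen without KO replicate 1 or KO replicate 3, and Pmaip1 without KO replicate 2 or KO replicate 3. Plk2 did not pass without WT replicate 2 or any 1 KO replicate, and Bbc3 passed without WT replicate 3 alone of the 6 fits that leave out 1 library (highest limma adjusted p = 0.0979 and 0.120). Skeletal muscle transcripts were high in KO replicate 1, by 2.95 log2 units over the WT mean.

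The interferon response list held 10 tested genes, of which 3 fell and 7 did not pass over all genes (10 fell when adjusted over the list alone). With edgeR 3 fell and with DESeq2 4, and DESeq2 gave Oasl2 no adjusted p. The median log2 fold change was -2.17 (camera adjusted p = 1.0e-09; adjusted p = 0.394 with an estimated correlation). Besides Isg15, Irf7, a transcription factor of the interferon pathway, went from 20.7, 243 and 83.6 in WT to between 3.25 and 4.76 in KO (log2 fold change -4.00 ± 0.70 (SE), limma adjusted p = 0.0171). Oasl2, a 2'-5'-oligoadenylate synthetase-like protein, went from 23.6, 312 and 32.7 to between 0.953 and 2.17 (log2 fold change -4.63 ± 0.81 (SE), limma adjusted p = 0.0171). Ifi27l2a, an interferon-induced gene outside the list, fell most among the genes named by rule, from 707, 5007 and 1366 to between 10.8 and 28.4, or 87.2-fold (limma adjusted p = 0.00113). WT replicate 2 stood apart, with the list 1.71 log2 units above the WT mean, and WT replicates 1 and 3 lay at -1.33 and -0.38, against -2.92 to -2.39 in KO. Without WT replicate 2 the median was -1.26 and 2 members fell, without WT replicate 1 6 fell, and without KO replicate 1 or KO replicate 3 1 fell. Irf7 did not pass without WT replicate 2, WT replicate 3, KO replicate 1 or KO replicate 3 (highest limma adjusted p = 0.0697), and Oasl2 without KO replicate 1 or KO replicate 3 (highest 0.0761). Isg15 passed in each of those fits, and did not pass with robust variance moderation (limma adjusted p = 0.114).

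**Figure D1:**
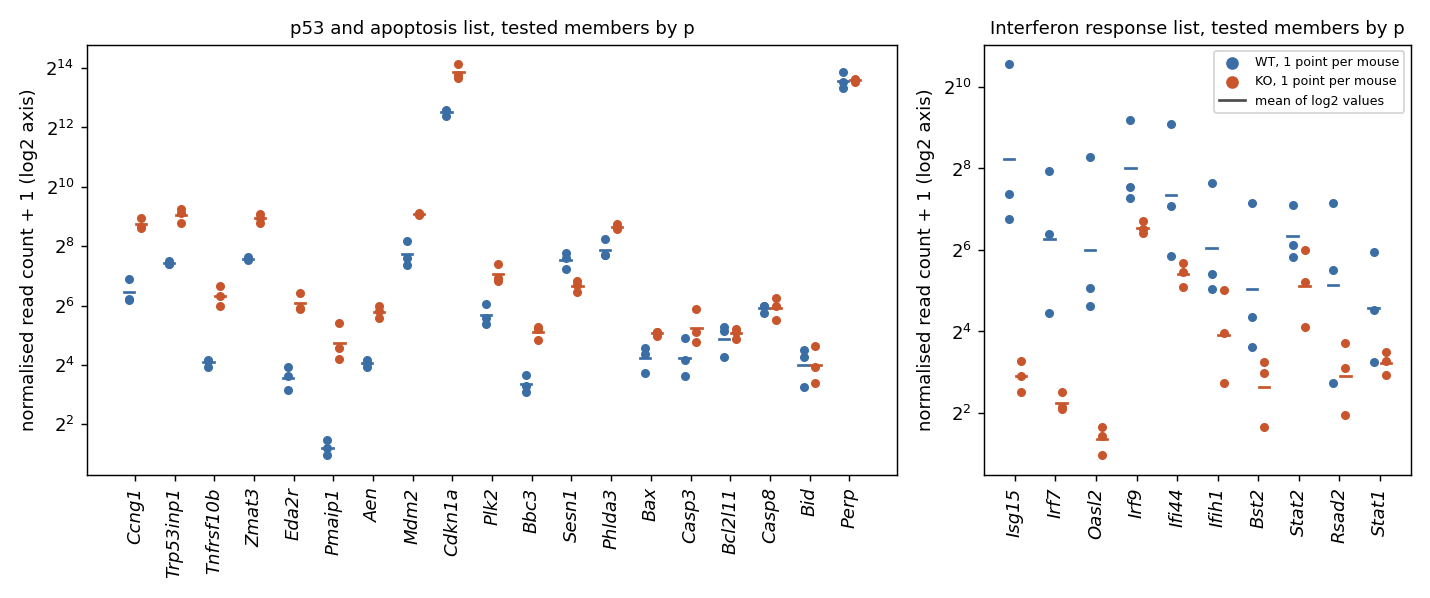
Normalised read count + 1 on a log2 axis for the tested members of the p53 and apoptosis list (19 genes) and of the interferon response list (10 genes), ordered by p, with 1 point per mouse and a bar at the mean of the log2 values of each group. The KO points of Ccng1 lie at 391 to 498 and the WT points at 72.6 to 118, and for Isg15 the WT library at 1508 is WT replicate 2.

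Among the other genes with the highest rises, Cpt1c, the brain form of carnitine palmitoyltransferase 1, went from 15.9 ± 12.9 to 170.0 ± 25.5 (log2 fold change 3.65 ± 0.49 (SE), limma adjusted p = 0.00510). Sulf2, which removes sulfate from heparan sulfate, rose by 3.06 on the log2 scale, Spink12, a Kazal-type protease inhibitor, by 2.76, Ptp4a3, a phosphatase, by 2.72, and Ddit4l, an inhibitor of mTOR signalling, by 2.66 (limma adjusted p from 0.00113 to 0.00380). Klk6, a kallikrein protease, rose by 3.48 on the log2 scale. It passed without WT replicate 3 alone of the 6 fits that leave out 1 library (highest limma adjusted p = 0.253), and neither edgeR (adjusted p = 0.0713) nor DESeq2 (0.206) called it. Adamtsl1, a secreted ADAMTS-like protein, fell from 212 ± 33.5 to 47.4 ± 7.71 (log2 fold change -2.13 ± 0.21 (SE), limma adjusted p = 0.00113). Frem2, a protein of the epidermal basement membrane, fell from 84.4 ± 22.9 to 18.7 ± 2.78 (limma adjusted p = 0.00489). Dcn, the collagen-binding proteoglycan decorin, fell from 1614 ± 266 to 423 ± 198 (limma adjusted p = 0.0152) and did not pass without WT replicate 2 (limma adjusted p = 0.0697). Alox15, a lipoxygenase, was 31.1, 246 and 28.7 in WT and 9.75, 2.59 and 0.953 in KO (limma adjusted p = 0.0453), and did not pass without WT replicate 2 or any 1 KO replicate (highest limma adjusted p = 0.152).

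Some stress and basal keratinocyte genes rose in KO. Sprr1b, a cornified envelope precursor made in stressed epithelium, rose from 4584 ± 804 to 10882 ± 1444 (log2 fold change 1.25 ± 0.21 (SE), limma adjusted p = 0.0157). Krt17, a keratin induced on wounding, rose from 5104 ± 1799 to 12568 ± 1749 (log2 fold change 1.35 ± 0.27 (SE), limma adjusted p = 0.0334), and Hbegf, a ligand of the EGF receptor, rose by 0.76. In the stress keratin and alarmin list 3 of 20 tested genes rose, 0 fell and 17 did not pass (7 rose when adjusted over the list alone; 8 rose with DESeq2), with a median log2 fold change of 0.62 (camera adjusted p = 1.1e-04; adjusted p = 0.496 with an estimated correlation). The mean of that list was -0.25, -0.24 and 0.48 log2 units from the WT mean in WT replicates 1 to 3. In KO it was 0.47 to 0.63, so WT replicate 3 lay within the KO range. Krt6b, another keratin of injured epithelium, was 61579 ± 10866 in WT and 139320 ± 8961 in KO (limma adjusted p = 0.106), and passed with edgeR (0.0421) and DESeq2 (1.7e-07). In the basal keratinocyte list 2 of 17 rose and 15 did not pass (7 rose and 3 fell when adjusted over the list alone; 5 rose and 2 fell with DESeq2), with a median of 0.51 (camera adjusted p = 0.00401; adjusted p = 0.496 with an estimated correlation). These were Itgb4, the hemidesmosome integrin subunit, from 341 ± 24.2 to 780 ± 212 (limma adjusted p = 0.0194), and Igfbp2, an IGF-binding protein, from 957 ± 82.2 to 1890 ± 449 (limma adjusted p = 0.0468). Itgb4 did not pass without WT replicate 1, WT replicate 2 or KO replicate 1, and Igfbp2 passed without KO replicate 3 alone of the 6 fits that leave out 1 library (highest limma adjusted p = 0.0812 and 0.182). Igfbp2 did not pass with edgeR (0.0516). The members did not move together: Krt14, the keratin whose promoter drives Cre, had a log2 fold change of 1.12 and Krt5, its partner, 1.04, while Krt15, a keratin of quiescent basal cells, had -1.25 (limma adjusted p = 0.0694, 0.118 and 0.123), and DESeq2 called each of the 3. The stress genes that rose numbered 1 without WT replicate 1 and 0 without WT replicate 2 or any 1 KO replicate. The basal genes that rose numbered 0 without WT replicate 1, WT replicate 2 or KO replicate 1 and 1 without WT replicate 3 or KO replicate 2. Without KO replicate 1 another basal gene fell and the basal list lost its camera call (median 0.17, adjusted p = 0.0871), as it did with a weight per library (0.0555). Sprr1b, Krt17 and Hbegf each passed without WT replicate 3 alone of those 6 fits (highest limma adjusted p = 0.0732, 0.140 and 0.187).

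**Figure D2:**
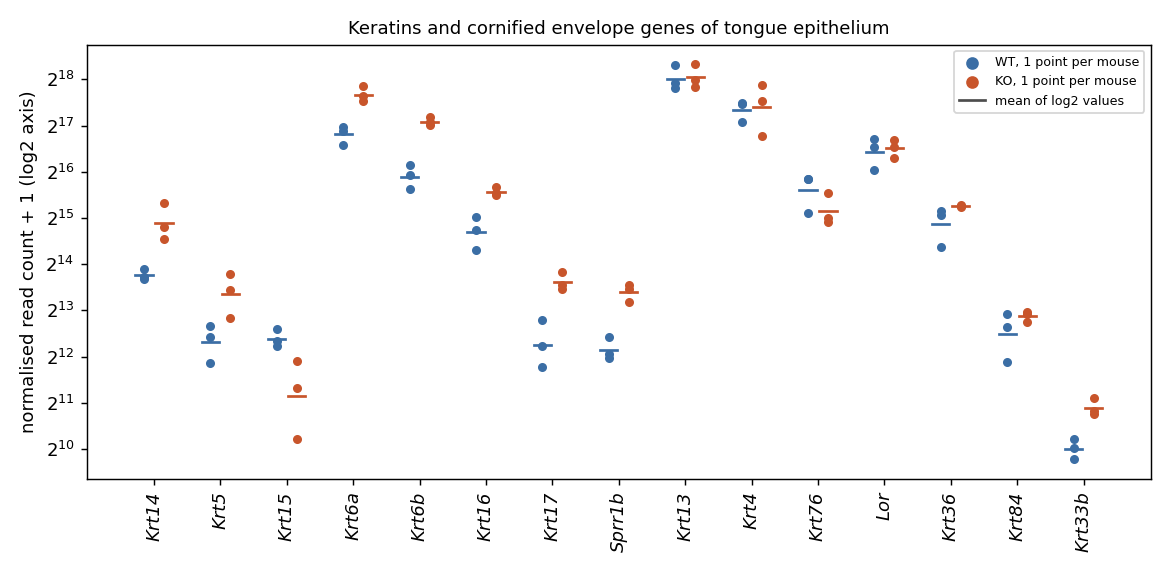
Normalised read count + 1 on a log2 axis for keratins and cornified envelope genes, with 1 point per mouse and a bar at the mean of the log2 values of each group. For Krt17 the WT points lie at 3475 to 7035 and the KO points at 11240 to 14549, and for Krt15 at 4815 to 6177 and 1183 to 3803.

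In the suprabasal and cornified list 0 of 29 tested genes passed with limma (0 adjusted over the list alone, 6 at an unadjusted p under 0.05), 0 with edgeR and 1 with DESeq2, Sprr1a. The median log2 fold change was 0.04 (camera adjusted p = 0.831). Its members with the lowest p were Casp14, a protease of cornifying cells (0.92, limma adjusted p = 0.127), and Sprr1a, a cornified envelope precursor (0.80, limma adjusted p = 0.165). In the list for the hard keratins of filiform papillae, the horny spines of the tongue, 1 of 15 rose and 2 fell (4 rose and 2 fell when adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.0668; adjusted p = 0.721 with an estimated correlation). The median was 0.14 without WT replicate 2. The hard keratins tested in the list all had a positive log2 fold change, from 0.30 for Krt34 to 0.89 for Krt33b. With limma over all genes only Krt33b of these passed. The 2 genes that fell, Lef1 and Selenbp1, are not keratins. That list passed camera without WT replicate 1 or KO replicate 1 (adjusted p = 0.00792 and 0.0432). It also passed with no filter, equal totals, quantile normalisation, DESeq2, the fibroblast and muscle covariate or the surrogate variable (camera adjusted p from 0.0202 to 0.0378). Krt33b, a hair-type keratin, rose from 1034 ± 151 to 1912 ± 264 (limma adjusted p = 0.0404), a call lost whichever library was left out and with edgeR (0.0515). Lef1, a transcription factor of Wnt signalling, fell from 156 ± 11.8 to 63.7 ± 7.06 (limma adjusted p = 0.00838) and passed whichever library was left out. Selenbp1, a selenium-binding protein, fell from 631 ± 118 to 215 ± 89.2 (limma adjusted p = 0.0273) and did not pass when KO replicate 3 or any 1 WT replicate was left out.

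The medians of the mitosis and S phase lists had opposite signs. In the mitosis list 0 of 29 tested genes passed with limma (2 fell when adjusted over the list alone, 12 had an unadjusted p under 0.05), 0 with edgeR and 2 with DESeq2, Cenpf and Kif23, both lower. The median log2 fold change was -0.55 (camera adjusted p = 1.3e-07; adjusted p = 0.394 with an estimated correlation), and -0.34 without WT replicate 2. Cenpf, a kinetochore protein, was 217 ± 34.4 in WT and 102 ± 30.9 in KO, and Kif23, a kinesin of cell division, 139 ± 32.6 and 72.1 ± 8.43 (limma adjusted p = 0.0589 and 0.0838). In the S phase list 0 of 26 passed with limma (0 adjusted over the list alone, 2 at an unadjusted p under 0.05), 0 with edgeR and 1 with DESeq2, Rrm1. The median was 0.44 (camera adjusted p = 8.2e-04; adjusted p = 0.496 with an estimated correlation), and the camera call was lost with a filter at 50 (adjusted p = 0.0508). Rrm2 and Rrm1, the subunits of ribonucleotide reductase, had log2 fold changes of 1.53 and 1.14 (limma adjusted p = 0.0918 and 0.129). KO replicate 1, in which muscle transcripts were high, was also the library with the highest S phase mean, 0.85 log2 units above the WT mean.

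In the list of sensors and transducers of the unfolded protein response 0 of 10 tested genes passed with limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05), edgeR or DESeq2, with a median log2 fold change of -0.08 (camera adjusted p = 0.828). The members with the lowest p were Mbtps2 and Atf6, the protease that activates ATF6 and ATF6 itself (-0.41 and -0.26). The lists for ER folding (0 of 22, median -0.16), ER-associated degradation (0 of 17, -0.03), ER N-glycosylation (0 of 15, -0.07) and ER-Golgi transport (0 of 27, 0.04) gave camera adjusted p of 0.626, 0.831, 0.944 and 0.999, each with 0 genes when adjusted over the list alone. At an unadjusted p under 0.05 they held 3, 0, 1 and 0 genes, and edgeR and DESeq2 called 0 in each. Hspa5, the ER chaperone BiP, was 4124 ± 400.1 in WT and 6962 ± 2510 in KO (log2 fold change 0.70, limma adjusted p = 0.230). Other members with the lowest p in these lists were Erp44 (-0.61), Dnajb9 (-0.74), Edem2 (-0.63), Ostc (-0.67) and Copg1 (-0.79), none of which passed. The ER translocation list had 0 of 22 genes passing with limma (0 adjusted over the list alone, 4 at an unadjusted p under 0.05), 0 with edgeR and 1 with DESeq2, Srp72. It had a median of -0.23 (camera adjusted p = 0.0205; adjusted p = 0.394 with an estimated correlation), and lost its camera call without KO replicate 1 (median -0.13, adjusted p = 0.0526) or KO replicate 3 (adjusted p = 0.0590) or with a filter at 50 (0.0503). In it Sec61b, a subunit of the translocation channel, had a log2 fold change of -1.23 and Srp72, of the signal recognition particle, 0.70 (limma adjusted p = 0.164 and 0.104). Sec61b passed without KO replicate 2 (limma adjusted p = 0.0440). Like Xbp1, it was highest in WT replicates 1 and 2 and KO replicate 2 (260, 286 and 160). The mean of the translocation list overlapped between the groups. WT replicate 3 lay at -0.14 and KO replicate 2 at -0.08 log2 units from the WT mean. Of 8 tested substrates of Ire1α-dependent mRNA decay, 1 rose (1 adjusted over the list alone), which was Tnfrsf10b, also counted in the p53 list. Cd59a, a complement inhibitor in the same list, had -1.06 (limma adjusted p = 0.199), and the list median was 0.23 (camera adjusted p = 0.313, and 0.0378 with no filter; adjusted p = 0.569 with an estimated correlation).

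In the integrated stress response list 2 of 35 tested genes rose and 33 did not pass (3 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 0.16 (camera adjusted p = 0.0227; adjusted p = 0.413 with an estimated correlation). Gdf15, a secreted stress cytokine that p53 also induces, rose from 3.60 ± 2.38 to 45.2 ± 12.5 (log2 fold change 3.48 ± 0.51 (SE), limma adjusted p = 0.00798). Sesn2, a sestrin, rose from 82.3 ± 5.92 to 158 ± 15.2 (limma adjusted p = 0.0350). Gdf15 did not pass without KO replicate 1 (limma adjusted p = 0.0577), and Sesn2 lost its call whichever library was left out (highest 0.128). So 0 members rose without KO replicate 1 and 1 without any other library. The camera call of the list was lost without WT replicate 2 (adjusted p = 0.0600) or KO replicate 1 (median 0.08, adjusted p = 0.0996). The ribosomal protein list, fixed by symbol, takes in 10 tested genes of other function such as the Rps6k kinases, and was also tested without these. Of the 75 left 1 fell (2 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 9.6e-12; adjusted p = 0.386 with an estimated correlation). With all 85 the median was -0.36 (camera adjusted p = 1.0e-09; adjusted p = 0.394 with an estimated correlation), and DESeq2 called 7, all lower. The gene that fell was Rpl5, a protein of the large ribosomal subunit, which fell from 691 ± 95.1 to 368 ± 62.0 (limma adjusted p = 0.0395). It passed without KO replicate 2 alone of the 6 fits that leave out 1 library (highest limma adjusted p = 0.145), where 3 members fell, and without WT replicate 1 another member rose. Without WT replicate 3 the median of the 75 was -0.20 and that of the 85 was -0.18.

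Among the remaining stress and metabolic lists the shifts were small. In the immediate early list 0 of 19 passed with limma (2 rose adjusted over the list alone, 4 had an unadjusted p under 0.05), 0 with edgeR and 1 with DESeq2, Btg2. The list, with a median of 0.20, had a camera adjusted p of 0.0148 (adjusted p = 0.394 with an estimated correlation). The camera call was lost without WT replicate 3 (adjusted p = 0.112) and the median was 0.34 without WT replicate 1. Btg2, an antiproliferative gene in it, had a log2 fold change of 0.86 (limma adjusted p = 0.0694, and 0.0476 without WT replicate 1). The lists of NRF2 targets (0 of 18, median 0.21) and of cholesterol and fatty acid synthesis (0 of 22, median -0.25), both with 0 genes adjusted over the list alone, 3 at an unadjusted p under 0.05 and 0 with edgeR or DESeq2, each had a camera adjusted p of 0.0432 (adjusted p = 0.394 and 0.569 with an estimated correlation). Osgin1 of the NRF2 list had 0.72 and Elovl6, a fatty acid elongase, -0.50, and neither passed. In the fit without WT replicate 3, 1 member of the NRF2 list rose. The NRF2 call was lost without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 (camera adjusted p from 0.0522 to 0.0952). It was also lost with edgeR, DESeq2, array weights or a filter at 50 (camera adjusted p = 0.0573, 0.0836, 0.0870 and 0.0975). The synthesis call was lost without WT replicate 2, WT replicate 3 or KO replicate 2 (camera adjusted p = 0.0600, 0.0820 and 0.396), with a median of -0.08 without KO replicate 2. It was also lost with edgeR, DESeq2, array weights, a filter at 50, the library name style or the Y-linked covariate (camera adjusted p from 0.0508 to 0.140).

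**Figure D3:**
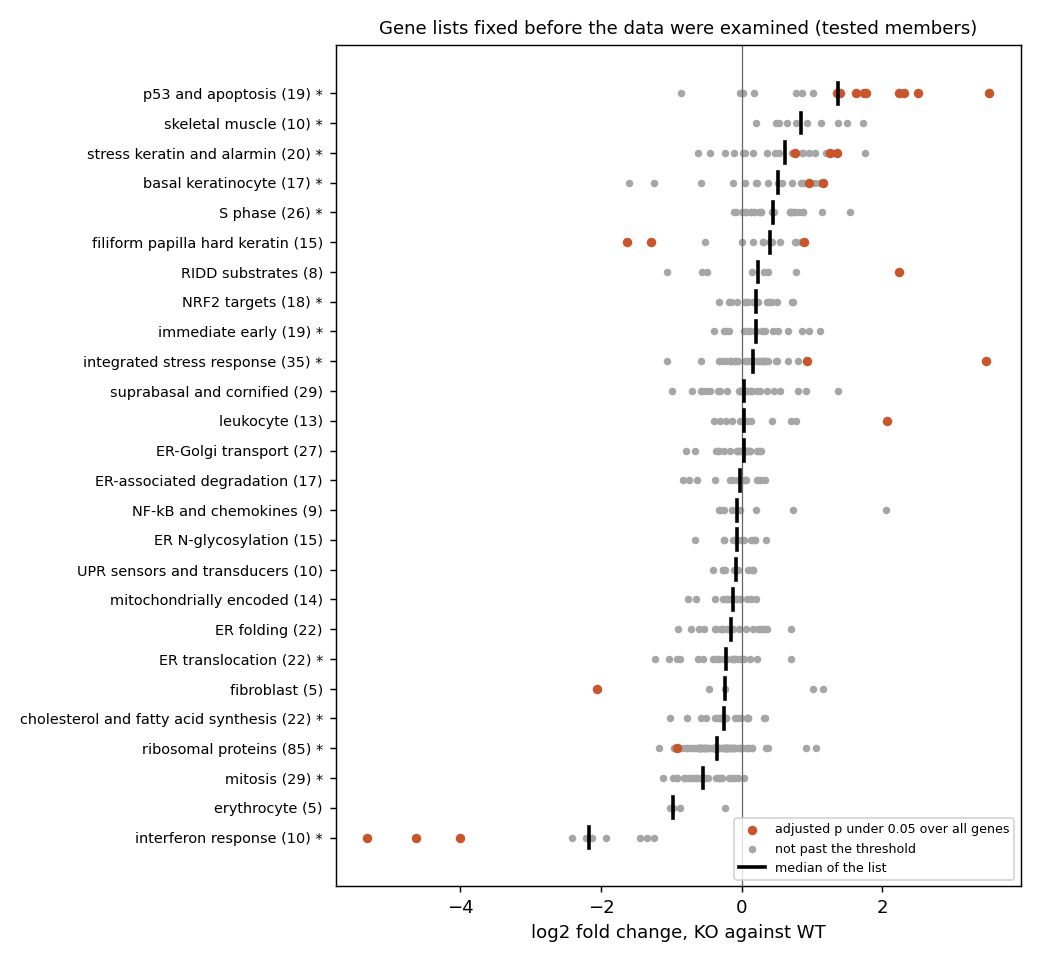
Log2 fold change of KO against WT for the tested members of 26 gene lists, with the number of tested members in brackets, red points for genes past the limma threshold over all genes, grey points for the rest, a black bar at the list median and a star for lists past the camera threshold with a preset correlation. The medians run from -2.17 for the interferon response list to 1.37 for the p53 and apoptosis list.

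Transcripts of other cell types differed between single libraries, while Dcn and Trbc2 separated the groups. The skeletal muscle list had 0 of 10 genes passing with limma (0 adjusted over the list alone, 3 at an unadjusted p under 0.05), 0 with edgeR and 1 with DESeq2, Ckm. It had a median log2 fold change of 0.85 (camera adjusted p = 0.0121; adjusted p = 0.683 with an estimated correlation). The median was -0.09 without KO replicate 1 (camera adjusted p = 0.842) and 1.87 without KO replicate 2. The call was also lost with the fibroblast and muscle covariate, the surrogate variable or a filter at 50 (camera adjusted p = 0.0774, 0.0827 and 0.0769). Tpm2, a tropomyosin, was 803 ± 80.3 in WT and 1191 ± 362 in KO (limma adjusted p = 0.312). In the fibroblast list 1 of 5 fell, Dcn (1 adjusted over the list alone; median -0.23, camera adjusted p = 0.3003). Without WT replicate 2 none fell, and without KO replicate 1 the median was -0.50 (camera adjusted p = 0.0139; with all libraries adjusted p = 0.721 with an estimated correlation). The fibroblast list mean was 1.29, -1.03 and -0.62 log2 units from the WT mean in KO replicates 1 to 3. Col1a2 and Col1a1 were 235 and 190 in KO replicate 1 and at most 21.7 and 14.3 in any other library. The fall of Dcn did not track these genes. The erythrocyte list (0 of 5, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 with edgeR or DESeq2) had a median of -0.98 (camera adjusted p = 0.203; adjusted p = 0.759 with an estimated correlation), -2.31 without KO replicate 1 (6.1e-08) and -1.75 with the fibroblast and muscle covariate (1.0e-04). With edgeR and DESeq2 its sign turned (0.52 and 0.56). In it Hbb-bs, a β-globin gene, was 294, 128 and 131 in WT and 531, 32.7 and 35.3 in KO (limma adjusted p = 0.686, and 0.0281 without KO replicate 1), so its group means, 184 and 200, run against its log2 fold change of -0.98. In the leukocyte list 1 of 13 rose (1 adjusted over the list alone; median 0.04, camera adjusted p = 0.166), which was Trbc2, a constant gene of the T cell receptor β chain, from 18.6 ± 5.77 to 78.7 ± 6.62 (limma adjusted p = 0.00601). Without WT replicate 2 the leukocyte median was 0.32 (camera adjusted p = 0.0134), and the list also passed with a filter at 50 (0.0481). With all libraries it had an adjusted p = 0.759 with an estimated correlation. Cd3e and Cd3g, also T cell genes of the list, were at most 2.17 in any library and were not tested. Ptprc, a gene of leukocytes in general, had a log2 fold change of -0.14 (limma adjusted p = 0.948). The rise of Trbc2 alone thus does not show more T cells in KO. The list of NF-kB targets and chemokines (0 of 9, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 with edgeR or DESeq2) had a median of -0.07, a mean of 0.21 and a camera adjusted p of 0.836. In it Icam1, an adhesion receptor, had a log2 fold change of 2.05 (limma adjusted p = 0.136, and 0.0270 without WT replicate 2). The mitochondrially encoded genes (0 of 14, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 with edgeR or DESeq2) had a median of -0.12 (camera adjusted p = 0.362), with mt-Tm, a mitochondrial tRNA gene, at -0.65.

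Lists with fewer than 5 tested members were not tested as sets. Mlana, a melanosome protein, rose from 0, 0 and 1.31 in WT to 26.0, 15.5 and 18.1 in KO (limma adjusted p = 0.0135) and did not pass when any 1 KO replicate was left out (highest limma adjusted p = 0.0998). It was 1 of 2 tested melanocyte genes, the other being Mitf (log2 fold change 0.58, limma adjusted p = 0.564). The other melanocyte genes of the list were too low to test, so the rise of Mlana does not speak for melanocyte transcripts in general. None of the 4 tested taste bud genes, 4 endothelial genes, 2 nerve and glia genes or the 1 salivary gland gene passed over all genes with limma, edgeR or DESeq2, and 2 endothelial genes had an unadjusted p under 0.05. Those with the lowest p were Pou2f3, a factor of taste receptor cells (log2 fold change -0.42), Flt1, a VEGF receptor (1.39), Ngfr, a nerve growth factor receptor (-0.54), and Amy1, an amylase (-0.43), with limma adjusted p of 0.419, 0.166, 0.440 and 0.633. Adjusted over the list alone, Mlana and Flt1 passed. The Y-linked gene Uty was 108, 0.873 and 102 in WT and 107, 112 and 2.86 in KO, so 1 library of each group had almost no Y-linked signal, and the labels give no sex.

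The authors' deposited table listed 341 genes with a q-value of at most 0.0495, of which 199 had a positive and 142 a negative log2 fold change. Of these, 321 were tested here, all 321 with the same sign, and 194 passed the limma threshold, 132 higher and 62 lower in KO. The number of the authors' genes passing was 124 without WT replicate 1, 77 without WT replicate 2, 73 without KO replicate 1, 103 without KO replicate 2 and 68 without KO replicate 3. Of the 198 genes called here, 4 were not in the authors' deposited table.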

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

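Of 89 genes picked by the rule or added to it, 53 passed, 30 of these passed without each library in turn and 29 in every fit; the surrogate variable and the fibroblast and muscle and Y-linked covariates were added after the values were seen. The number of changed genes was within 1.5 times of 198 with another pseudocount, filter or scaling, robust moderation, edgeR (190) or the fibroblast and muscle covariate (188). Array weights gave 590 (317 higher, 273 lower), DESeq2 371 (210 and 161; 338 of the authors' genes), the library name style, partly aligned with genotype, as a covariate 82 (61 and 21; 81 of the authors'), the Y-linked covariate 119 (84 and 35; 118) and 1 surrogate variable 508 (258 and 250; 301). Lists past the threshold numbered 8 of those left under a filter at 50, 0 with an estimated correlation and 1 with the directional test of fry. Without 1 library at a time, changed genes ran from 68 to 186, higher from 48 to 129, lower from 16 to 57 and the authors' genes passing from 68 to 158.

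Signs that turned were those of results not called, save skeletal muscle. With array weights these were ER N-glycosylation (0.045), ER folding (0.00809), ER-associated degradation (0.058), UPR sensors (0.078) and Uty (-0.50). With edgeR they were the erythrocyte list (0.52) and Hbb-bs (0.089), and with DESeq2 the erythrocyte list (0.56) and Hbb-bs (0.11), which got no adjusted p there. With the library name style they were ER N-glycosylation (0.0014) and fibroblast (0.0011). With the fibroblast and muscle covariate they were ER-Golgi transport (-0.016), leukocyte (-0.077) and suprabasal (-0.035). With the surrogate variable they were ER-Golgi transport (-0.00330), UPR sensors (0.022), suprabasal (-0.024) and Xbp1 (0.022). Without 1 library at a time the ranges were -1.55 to 2.00 for Uty, -0.70 to 0.033 for Xbp1, -0.083 to 0.098 for ER N-glycosylation and -0.036 to 0.041 for ER-Golgi transport. They were -0.11 to 0.042 for ER-associated degradation, -2.31 to 0.084 for erythrocyte, -0.50 to 0.18 for fibroblast, -0.14 to 0.32 for leukocyte, -0.27 to 0.062 for mitochondrially encoded genes, -0.092 to 1.87 for skeletal muscle and -0.072 to 0.14 for suprabasal. The cause was not tested.

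The replicate numbers do not pair the samples: correlations within a number were -0.25, 0.026 and 0.28, and the highest was 0.41, between WT replicate 1 and KO replicate 2. With a replicate block 178 genes changed, and of the 89 genes Sesn2, Bbc3, Hbegf and Krt33b lost their calls and Krt5 gained one. At these depths a value of 0 allows up to 2.59 to 3.92 normalised reads.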

Other observations

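Genes outside the lists and the naming rule also changed, and those here were chosen after their values were seen. Rnf169, a protein recruited to DNA double-strand breaks, rose from 161 ± 10.6 to 543 ± 44.8 (log2 fold change 1.75, limma adjusted p = 0.00113, n = 3 per group). Mgmt, which repairs alkylated guanine, rose by 1.96 on the log2 scale, Polk, a translesion DNA polymerase, by 1.88, and Zfp365, a zinc finger gene linked to genome stability, by 2.61. Ephx1, an epoxide hydrolase, rose by 2.24. Mcam, a cell adhesion receptor, rose from 3.63 ± 1.76 to 80.1 ± 26.8 and Cd55, a complement regulator, from 2.23 ± 1.13 to 54.9 ± 7.96. Sox9, a transcription factor, rose by 1.97, Cald1, an actin-binding protein, by 1.99, and Fscn1, an actin-bundling protein, by 2.84. Foxp2, a forkhead transcription factor, fell from 389 ± 85.1 to 112 ± 27.4, Hs3st5, a heparan sulfate sulfotransferase, from 106 ± 5.80 to 29.0 ± 5.47, and Pir, an iron-binding nuclear protein, from 752 ± 109 to 285 ± 42.9. All 13 had a limma adjusted p of at most 0.00510, and no theme is claimed for them.

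The p53 and interferon patterns were picked after a first look at the values, and so were the tests of fibroblast and muscle cells, of Cre and of WT replicate 2. The tests of handling and of leukocytes, and the count of splits, were written before those values were seen. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 198 genes and the highest other gave 151, and 10 splits are too few for a share under 0.05. That other split put WT replicates 1 and 2 with KO replicate 2, and the surrogate variable orders the libraries the same way, so the samples hold a structure besides genotype.

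The rise of p53 targets may come from loss of Ire1α, from Cre activity, from fibroblast and muscle cells carried along or from handling. With the fibroblast and muscle level as a covariate the median of the p53 list was 1.3458, so fibroblast and muscle cells do not account for it, and other cell types were not used as covariates. Handling and digestion would raise immediate early genes, and their median was 0.2028 against 1.37 (SE of the difference 0.261, over list members and not mice). The immediate early list did rise (camera adjusted p = 0.0148, and 0.394 with an estimated correlation). Handling need not raise both lists by equal amounts, so the smaller rise cannot exclude it. Cre in the nucleus can break DNA and so induce p53 targets, and the design holds 0 groups with Cre and without loss of Ire1α, so this cannot be told from loss of Ire1α. Cre-positive mice without floxed alleles would tell them apart.

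The lower interferon response in KO could come from WT replicate 2 alone, from fewer leukocytes, or from genotype or exposure differing between mice. Without WT replicate 2 the median was -1.2607 and 2 of 10 members fell (camera adjusted p = 1.6e-08 at the preset correlation; with all libraries the list had an adjusted p = 0.394 with an estimated correlation). Over the 10 tested members the other WT libraries thus also lay above KO on average. The filter asked for a value of at least 10 in at least 3 libraries. A member under 10 in every KO library was therefore tested only if WT replicates 1 and 3 also reached 10. Of 24 listed members 10 were tested. Ddx58, high in WT replicate 2 alone (90.8), was left out, as was Rtp4, high in WT replicates 2 and 3 (350 and 83.6). The tested members were thus partly chosen by these libraries, so the fit cannot exclude WT replicate 2 alone. The leukocyte list without class II genes, 9 genes, had a median of 0.038632 against -2.17 (SE of the difference 0.530). The mean of the full leukocyte list was -0.52, 0.49 and 0.03 log2 units from the WT mean in WT replicates 1 to 3. In KO replicates 1 to 3 it was 0.61, -0.02 and 0.14, so these transcripts were not lower in KO. The SE is over list members, which are correlated (0.455 for leukocyte, 0.784 for interferon response), not over mice, so it cannot exclude fewer leukocytes. Genotype and a difference in exposure between the mice also stay open.

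The genes listed at 0 in every library were noticed in the values, and both tests here were chosen after that. Of protein-coding genes wholly inside another, 99.6% were at 0, on the same strand (378 of 380) as on the opposite strand (536 of 538). This would follow if reads were counted over whole gene bodies on either strand and shared reads dropped. The enclosed ribosomal protein genes, Rpl13, Rpl35 and Rps27rt, were at 0 (3 of 3 or 100%), against 5 of 82, or 6.1%, of the others. This argues against silence as the sole cause, but so few genes cannot speak for every enclosed gene.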
